A study of Rattus norvegicus with 2 samples.

How the data were processed

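Hepatic RNA of rats made diabetic with streptozotocin, a toxin of the insulin-producing beta cells, was compared on 2 arrays after treatment with γ-conglutin, a seed protein of lupins, or with saline alone. Per the labels' protocols, male Wistar rats received 65 mg/kg streptozotocin, and diabetes was defined as a glycaemia above 200 mg/dl at 72 h. They then received 120 mg/kg γ-conglutin in 0.9% saline, or the saline, for 7 days. Per the series' design text, equal amounts of liver RNA of 5 rats were pooled per group before cDNA synthesis, and the hybridisation of the 2 pools was repeated with the dyes exchanged. Per the labels, the control pool carried Alexa555 and the treated pool Alexa647 on array 1, and the reverse on array 2. The channel tags in the file headers give the same orientation. Both arrays hold the same 2 RNA pools, so they count as 1 replicate, with no replicate between animals, and no p-value was computed.

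The array names mouse genes with mouse symbols, while the RNA is from rat. Of 16208 measured named genes, 10105 (62.3%) have a rat gene of the same symbol in the GRCr8 gene table and 915 match a rat synonym. The array's own symbols were kept. Probe sequences were not analysed here, so how well each mouse probe binds its rat transcript is unknown.

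Per the file headers, the deposited scanner tables give for each spot and channel the mean raw intensity, the mean and SD of the local background intensity, a net intensity and a ratio of the net intensities. The values show that the deposited net intensity of Alexa555 is raw minus background with negative differences set to 0. That of Alexa647 was in addition rescaled by a factor that varies from spot to spot. The method of that rescaling, the scanner and its software are not given in the sources used here. The deposited value table holds log2 of the ratio of Alexa555 over rescaled Alexa647 on both arrays, with a largest difference of 4.4e-09 from the scanner column. Its scale and direction are thereby settled, and its medians over the probe spots were 0.00026 on array 1 and 0.022 on array 2.

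The raw and background intensities were the starting point here. Background was corrected with normexp (offset 50) and each array was normalised by loess over all spots, with empty spots at weight 0, in limma 3.58.1 under R 4.3.3. Each log2 ratio was turned to treated over control by the dyes in the labels, and the mean of the arrays was taken, in which a dye effect cancels. Later steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A spot counted as measured when raw minus background exceeded the 95th percentile of the 1235 empty spots in at least 1 channel on each array. This limit was set after the data were seen, because 77.4% of the empty spots lay over 2 SD above their local background in the Alexa555 channel of array 1. Spots of a gene were averaged. Spots without a symbol were kept as single features. Saturated spots were kept, 3 in the Alexa647 channel of each array.

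The remaining choices in this paragraph were made before the data were examined. A gene was called higher or lower when its log2 ratio reached 1.5-fold (0.58) in the same direction on each array, and dye-following when it reached 1.5-fold in opposite directions after turning. Genes were named by a fixed rule. It took the 12 with the largest and the 12 with the most negative ratio by the smaller of the arrays' values, same sign on both, without clone or predicted-gene names. In each of 37 gene lists it took the members that met the size rule, up to 4, or else the 2 with the largest absolute mean. It added 20 metabolic symbols, of which 17 were measured, and some of these are not reported here. A list's median was placed among 10000 random lists of the same size, matched on brightness in 20 bins, as a description of these pools.

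The steps were tested on simulated arrays with 200 genes altered by known folds in 19380 features. The altered genes were drawn without the dimmest spots, so recovery among these was not simulated. Within that limit the size rule recovered 100% of the 3-fold, 84% of the 2-fold and 12% of the 1.5-fold alterations. It recovered 0% of those 25% above equal, and it called 1 of 19180 unaltered features. The simulated dye and noise parts were these arrays' own ratios, reshuffled among spots of like brightness. The count of false calls is therefore no independent test of the rule. The simulation also took the dye labels as right and let each probe report the full fold of its gene, so recovery may be lower in the data. The list step was tested on the measured values instead, each list being placed among 200 random lists only. Of 200 random lists of 25 genes, 7% fell outside the central 95% of random lists. Of 100 lists with 0.1 added to their median, 98% lay above it.

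The alternatives were no background correction, plain subtraction, print-tip loess (a loess in each of the 48 print blocks), median centring, Aquantile, no filter on dim probes, a filter on both channels, the deposited value table, the brightest probe of a gene, each array alone, and other size rules. A limit of 2 SD over the local background was added after the data were seen. No sample was left out.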

Results

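Liver transcripts of streptozotocin-diabetic rats treated for 7 days with γ-conglutin were set against those of saline-treated diabetic rats, as 2 pools of 5 rats on 2 dye-exchanged arrays. The study's title names the modulation of the hepatic transcriptome by γ-conglutin as its subject. Each array carries 23232 spots, of which 1235 are empty. Of the 21997 probe spots, 20815 (94.6%) were measured, giving 19380 features with 16208 named genes. The median raw intensity of probe spots ranged from 1201 to 1720 over the 4 channels, against medians of 41.3 to 51.3 in empty spots. The number of arrays limits the precision, and there is no replicate between animals. All signed values are log2 of treated over control, with the direction taken from the dyes in the labels.

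No gene was 1.5-fold higher and no gene was 1.5-fold lower in the γ-conglutin pool on both arrays. By the smaller of the arrays' values, the most negative named genes were Mcts1, a translation re-initiation factor, at -0.61 (-0.53 and -0.70 on arrays 1 and 2), and Zscan21, a zinc finger gene, at -0.56 (-0.63 and -0.50). Prss16, a thymic serine protease, had -0.78, with -0.49 and -1.07 on the arrays. At the other end, Krtap5-1, a keratin-associated protein gene, had 0.41 (0.47 and 0.34), a ratio of 1.33. Bmp10, a ligand of the bone morphogenetic protein family, had 0.32 (0.35 and 0.29). This ranking rests on the labelled dyes of both arrays. The central 95% of the features lay between 0.81 and 1.14 times control.

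The other most negative genes were Abcd2, a peroxisomal fatty acid transporter (-0.46), Oit3 (-0.46), Prrg2 (-0.45), Pclo (-0.46), Capn11 (-0.43), Chd6, a chromatin remodeller (-0.44), Zbtb46 (-0.40), Reep6 (-0.42) and Dus3l (-0.41). Abcd2 had -0.46 on each array, and Oit3 had -0.49 and -0.42. The other largest ratios were those of Spen (0.30), Rragd, a GTPase of the mTORC1 pathway (0.28), Srf, the serum response factor (0.27), Mesdc1 (0.32), Ankrd1 (0.31), Fkbp6 (0.31), Dgcr2 (0.25), Tbrg4 (0.24), Nap1l1 (0.24) and Mrpl55 (0.27). Each of these 24 genes is read by a single measured spot. Each kept its sign without background correction, with plain subtraction, print-tip loess or median centring, and in the deposited value table. The size moved by over 1.5 times for Chd6 (-0.21 with no filter on dim probes), Zbtb46 (-0.26 with print-tip loess), Spen (0.20 with print-tip loess) and Dgcr2 (0.14 with median centring).

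**Figure D1:**
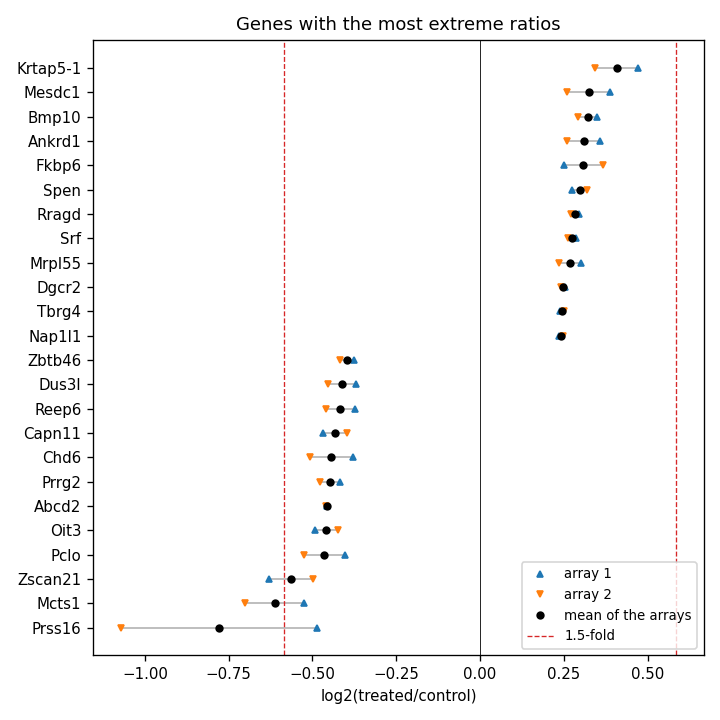
Log2 ratios of treated over control (horizontal axis) for the 24 genes with extreme ratios, with triangles for each array, circles for their mean and dashed lines at 1.5-fold. Mcts1, at -0.61, passes a dashed line with its mean but not with its array 1 value of -0.53.

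Of the metabolic genes fixed in advance, G6pc, the catalytic subunit of glucose-6-phosphatase, had -0.06 (-0.17 and 0.05 on arrays 1 and 2), Pck1, the cytosolic phosphoenolpyruvate carboxykinase, had 0.03 (0.22 and -0.16), and Fbp1 had 0.16 (0.10 and 0.23). The glucose transporter gene Slc2a2 had -0.05 (0.05 and -0.15). G6pc, Pck1 and Slc2a2 thus had opposite signs on the arrays. Of the insulin signalling genes, Insr had 0.10 (0.22 and -0.02), Irs2 had 0.05 (0.07 and 0.04) and Akt2 had -0.09 (-0.30 and 0.11). Irs1 had -0.01 (-0.26 and 0.24) and turned positive with print-tip loess and in the deposited value table. Values moved by over 1.5 times for Insr (0.18 with plain subtraction, 0.06 with print-tip loess), and with print-tip loess for Pck1 (0.05), Irs2 (0.03) and Akt2 (-0.06). In the deposited value table Pck1 (0.07), Irs2 (0.03) and Akt2 (-0.05) moved by over 1.5 times as well.

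The lipogenic regulator Srebf1 had 0.12 (0.25 and -0.003 on the arrays), and Fasn, the fatty acid synthase, had 0.03 (-0.01 and 0.07), and 0.05 with print-tip loess. Ppara, a regulator of fatty acid oxidation, had 0.12, with 0.37 and -0.14 on the arrays. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 0.03 (0.10 and -0.04). Igf1 had -0.18 (-0.04 and -0.33), and -0.10 with print-tip loess. Cpt1a (0.19 and -0.14 on the arrays) and Ppargc1a (-0.24 and 0.28) both had a mean of 0.02, with a sign that depended on the normalisation: Cpt1a was negative with print-tip loess, and Ppargc1a without background correction and with plain subtraction. Foxo1 was not well above background, at a print position that was dark in at least 10 of the 48 blocks, and Igfbp1 has no probe under that symbol. Several of these metabolic probes were dim, at brightness percentiles 0.26 (Ppargc1a), 2.89 (Insr), 7.24 (Slc2a2), 9.68 (G6pc), 15.0 (Irs1), 16.7 (Pck1), 16.8 (Fbp1) and 19.2 (Fasn). Ppargc1a, Insr and Slc2a2 lay below the brightness that the simulated alterations covered.

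No feature among the 19380 met the size rule, so none of the 957 measured entries in the 37 gene lists could. List medians ran from -0.05 to 0.05. The random lists were matched on brightness but not on print position. Over the rows of print blocks, the median ratio ran from -0.03 to 0.04. Probes of a gene shared little on this array, as given below, so a median near 0 does not show an unaltered pathway. Among the metabolic lists, gluconeogenesis had a median of 0.03 over 14 genes, at percentile 71.8 of the random lists. Its largest absolute means were those of Pck2 (-0.33; -0.72 and 0.06 on the arrays) and Slc25a10 (-0.20; -0.03 and -0.37). Glycolysis and glucose uptake had -0.02 over 21 genes (0.01 on array 1 and -0.12 on array 2), with Pfkm, a phosphofructokinase, at -0.29 (-0.23 and -0.34) and Khk, the ketohexokinase, at -0.25 (-0.07 and -0.43). Insulin signalling had 0.04 over 35 genes, at percentile 94.6, with -0.02 and 0.05 on the arrays. Lipogenesis and triglyceride synthesis had 0.03 over 28 genes, with Lpin3 at -0.35 (-0.65 and -0.04) and Pnpla3 at -0.25 (-0.40 and -0.09). Fatty acid oxidation and ketogenesis had 0.02 over 34 genes (0.05 and -0.05 on the arrays), with Acox2 at -0.26 (-0.07 and -0.46). The lipoprotein list had -0.03 over 21 genes (-0.07 and 0.003 on the arrays), at percentile 4.09. Its median was -0.016 with print-tip loess and -0.006 at its highest over the normalisations. In this list Mttp, which loads lipid onto apolipoprotein B, had -0.25 (-0.18 and -0.32).

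Outside the central 95% of random lists lay 3 lists, where 1.85 of the 37 are expected by chance at the nominal 5%. In the test with random lists of measured genes 7% lay outside, against the nominal 5%. The list of AMPK, sirtuins and autophagy had the highest median, 0.05 over 26 genes (percentile 98.6), with Atg7 at 0.17 (0.02 and 0.33) and Gabarapl1 at -0.24 (-0.09 and -0.39). Its median was 0.05 on array 1 and 0.03 on array 2, and it lay inside the random lists at 0.04 with median centring and at 0.03 with no filter on dim probes. Cytosolic ribosomal proteins had -0.02 over 72 genes (percentile 0.81), with Rps20 at -0.34 (-0.38 and -0.29) and Rps25 at -0.42 (0.14 and -0.99). Pancreatic markers had -0.04 over 21 genes (percentile 2.22). The ribosomal median was -0.01 on array 1 and 0.01 on array 2, and the pancreatic median -0.07 and 0.01, so neither had the same sign on both. None of the 3 lay outside random lists on either array alone. The pancreatic list lay inside them under 5 of 10 alternatives with both arrays, the AMPK list under 3 and the ribosomal list under 0. Of these alternatives, Aquantile leaves each ratio as it is by design, so its outcome was fixed. The brightest probe and the filter on both channels also left these 3 medians as they were.

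**Figure D2:**
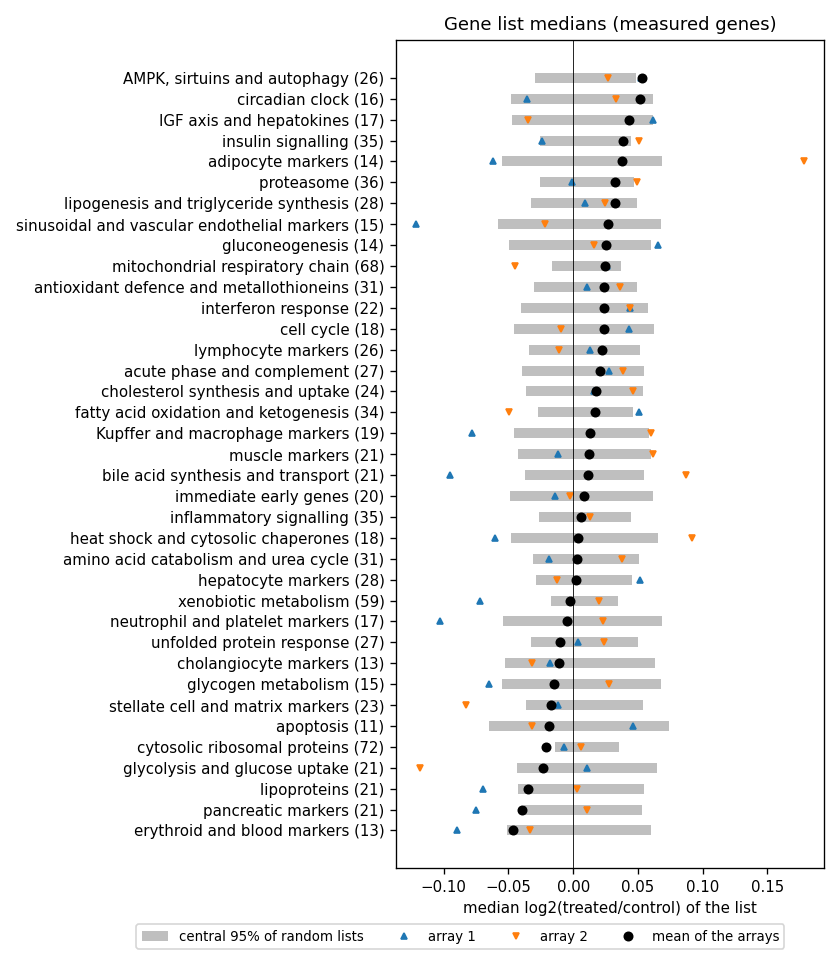
Median log2 ratio of treated over control for the 37 gene lists (measured genes in parentheses), with triangles for each array, circles for the mean of the arrays and grey bars for the central 95% of random lists matched on brightness. The medians lie between -0.05 and 0.05, and 3 lie outside their grey bar.

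Stress and inflammation lists also had medians near 0. The acute phase and complement list had 0.02 over 27 genes and the interferon response 0.02 over 22. The inflammatory signalling list had 0.01 over 35 genes, 0.03 with print-tip loess and 0.05 at its highest over the normalisations. In this list the chemokine gene Cxcl1 had 0.27 (0.19 and 0.36 on the arrays). Rela, a subunit of NF-κB, had -0.35 (-0.52 and -0.18), and -0.20 with print-tip loess. Antioxidant defence and metallothioneins had 0.02 over 31 genes, with Mt3 at -0.45 (-0.18 and -0.71) and Prdx5 at -0.37 (0.17 and -0.92). Per3, of the circadian clock list (0.05 over 16 genes), had 0.33 (0.20 and 0.46), and Nr1d2 of the same list had -0.39 (-0.17 and -0.61). In the mitochondrial respiratory chain (0.02 over 68 genes), Cox5b had -0.43 (-0.53 and -0.33). The apoptosis list had -0.02 over 11 of its 33 genes on the array and the cell cycle list 0.02 over 18 of 36. Every unmeasured gene of these lists, 22 and 18, lies at such dark print positions, so their absence gives no level. The medians of the circadian (-0.04 and 0.03), respiratory chain (0.03 and -0.05), apoptosis (0.05 and -0.03) and cell cycle lists (0.04 and -0.01) had opposite signs on the arrays. Casp6, a caspase of the apoptosis list, had -0.43 (-0.36 and -0.50), Gdf15, a stress-responsive cytokine, -0.41 (-0.54 and -0.28), and the xenobiotic-metabolising Cyp2e1 had -0.27 (-0.23 and -0.30).

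Markers of the cell types of the liver gave medians of 0.00 for hepatocytes over 28 genes (0.05 and -0.01 on arrays 1 and 2) and 0.01 for Kupffer cells and macrophages over 19 (-0.08 and 0.06). Those for stellate cells and matrix had -0.02 over 23 (-0.01 and -0.08) and those for lymphocytes 0.02 over 26 (0.01 and -0.01). Endothelial markers had 0.03 over 15 genes, while their medians on the single arrays were negative, at -0.12 and -0.02. The medians for hepatocytes and stellate cells took the other sign under 1 of the 5 other normalisations. In this liver RNA the hepatocyte probes had a median log2 brightness of 10.6, against 10.7 over all features. Their brightness thus did not mark them as liver genes, so these medians decide nothing about the cell composition. The erythroid and blood list had -0.05 over 13 genes (-0.09 and -0.03), at percentile 3.34. In these lists Col4a2, a basement membrane collagen, had -0.41 (-0.26 and -0.57 on the arrays), Cd3d, a chain of the T cell receptor complex, had -0.30 (-0.29 and -0.31) and Clec4g had -0.26 (-0.27 and -0.24). The naming rule also took members with positive means: the matrix proteoglycan gene Bgn (0.23; -0.27 and 0.73), Il2rb (0.17; -0.26 and 0.59), Serpina1b (0.14; 0.22 and 0.07) and Ambp (0.14; 0.03 and 0.25).

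The arrays of the pair opposed each other. Across the 19380 features, which are not independent replicates, the turned ratios correlated with r = -0.43 (Spearman's rho = -0.45), so that they correlated positively before turning. Ratios had the same sign on both arrays for 33.3% of the features. At 1.5-fold, 31 features were dye-following, 16 of them brighter in Alexa555 and 15 brighter in Alexa647. Among them, singled out after their values were seen, were Sgce (-0.84 and 0.88 on the arrays), Ptbp2 (-0.78 and 0.75) and Fbxw5 (0.74 and -1.14). Sgce and Ptbp2 were among the dimmest measured features, at brightness percentiles 0.25 and 1.56, and Fbxw5 lay at 75.2. On the single arrays, 57 features were 1.5-fold higher and 123 lower on array 1, and 135 higher and 474 lower on array 2. If the dyes of 1 array were named wrongly, the treatment and dye parts of each value would change places, and the dye-following features would head the ranking in place of Mcts1 and Krtap5-1.

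Control spots and repeated probes bear on the precision and on the gene names. The 227 measured Gapdh spots had a mean of -0.22 with an SD of 0.07 over spots (-0.28 on array 1 and -0.17 on array 2), and -0.11 with print-tip loess. This glycolytic gene was singled out after its values were seen, and its mean was negative under each normalisation tried, given the labelled dyes. Different probes of the same gene shared little: over 1163 probe pairs of 908 genes, mean ratios correlated with r = 0.02 and brightness with r = 0.05, where shuffled pairs gave -0.06 to 0.06. Gene names are those of the scanner files. The probe pairs are a partial test of these names, and they gave the names no support, as pairs agreed no better than shuffled ones. Whether a given spot reports the gene it names was not tested further. Each value given for a gene is therefore that of the probe bearing its name, and readings at the level of genes or lists lack support from second probes.

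**Figure D3:**
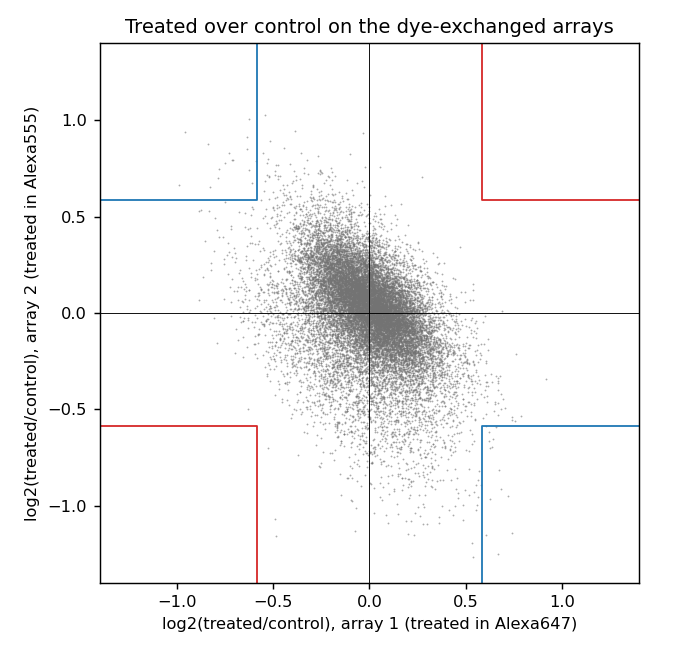
Log2 ratio of treated over control on array 1 (horizontal axis) against array 2 (vertical axis) for 19380 features, 1 point per feature, with red corners for 1.5-fold in the same direction and blue corners for opposite directions. The cloud slopes downward (r = -0.43), the red corners hold 0 features and the blue corners 31.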

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

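The empty spots carried signal. Of the 1235 spots without a probe, 384 (31.09%) lay over 2 SD above their local background in both channels of both arrays, against 97.7% of the probe spots. The brightest empty spot had 3614 above background in the Alexa555 channel of array 1, where 6 empty spots exceeded 500. The source of this signal was not tested.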

How the results depend on the processing

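The counts of genes 1.5-fold higher and lower on both arrays stayed at 0 under each background correction, normalisation, dim-probe filter and probe rule, including the 2 SD filter chosen after seeing the data. With 1 array alone they were 57 to 135 higher and 123 to 474 lower. Other size rules gave 1 higher (Krtap5-1) and 53 lower at a fold 25% above equal on each array, 0 higher and 4 lower for the mean of the arrays at 1.5-fold, and 162 higher and 803 lower at 2 local SD over brightness. The 4 were 4930587E11Rik, Prss16, Mcts1 and Phlda1. The 53 had a median log2 brightness of 13.7, against 10.7 over all features. Of them, 7 were T cell receptor beta chain probes described as sequences of infected or uninfected mice. Of the 965 genes beyond 2 local SD, 716 (74.2%) had the same sign on both arrays, against 33.3% of all features. Choosing genes by an extreme mean favours the same sign, so this share does not measure agreement. Dye-following features numbered 31, and 72 with plain subtraction, 15 with print-tip loess, 469 with median centring, 53 in the deposited value table, 0 at 2-fold, 642 at 25% above equal, 124 by the mean and 879 by local SD. The correlation between the arrays stayed negative, at -0.468 with plain subtraction, -0.299 with print-tip loess, -0.667 with median centring and -0.351 in the value table. The number of lists outside random lists was 3. It was 2 without background correction, with plain subtraction, with median centring, with no filter on dim probes and with the 2 SD filter, 4 in the value table, and 5 with print-tip loess and 5 with the brightest probe. On a single array it was 3 or 4. With 1 array alone the median of pancreatic markers ranged from -0.075 to 0.0106 and that of cytosolic ribosomal proteins from -0.0074 to 0.0062, both taking the other sign on array 2. Of the 37 list medians, 26 kept their sign under the 5 other normalisations, while 15 took the other sign without array 1 and 14 without array 2. Aquantile moved no ratio, as it aligns only the brightness of the arrays. The causes were not tested. Signal over background left 94.6% of probe spots measured, but gave no value for 22 of 33 apoptosis genes and 18 of 36 cell cycle genes.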

Other observations

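All tests in this part were chosen after the results were seen. By the labelled dyes, a subset of the T cell receptor beta chain probes stood lower in the treated pool. This subset, the 98 measured probes described as beta chain sequences of infected or uninfected mice, lies in 42 of the 48 blocks and had a median of -0.27 (-0.38 on array 1 and -0.17 on array 2). Within the blocks it lies in spot rows 8 to 11 only, where 3917 other spots had a median of 0.002 with an SD of 0.13. On both arrays 72 of the 98 probes were lower, 73.5% against 16.6% of all measured spots. With the dyes of 1 array exchanged, the array medians would have opposite signs. The other T cell receptor beta probes, 378 in number, had a median of -0.05 with an SD of 0.13, and 118 of them were lower on both arrays. Alpha chain probes had 0.03 over 218 and immunoglobulin probes -0.004 over 1355.

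A gradient across blocks and a general property of bright spots were tested for this subset. Print-tip loess left its median at -0.2686, and other spots of the same brightness had 0.01505, which argues against both. Fewer lymphocytes in the treated livers may lower such probes. The lymphocyte marker list had 0.02209, but the probes of a gene did not share brightness on this array (r = 0.05), so the marker list decides nothing. The other beta chain, the alpha chain and the immunoglobulin probes, at -0.05, 0.03 and -0.004, were not lowered to that extent. The same limit on probe names holds for these groups. A sequence that these probes may share, and a dye effect if the labels of 1 array are wrong, stay open, untested.

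By the labelled dyes, Gapdh spots were lower in the treated pool on both arrays in 213 of 227 cases, and with the dyes of 1 array exchanged their array means (-0.28 and -0.17) would have opposite signs. They lie almost all, 226 of 227, in 4 blocks. Their mean of -0.22 was -0.1101 after print-tip loess, which argues against a gradient across blocks as the whole cause. Over 1516 neighbouring spots the median was -0.19 on array 1 and 0.14 on array 2, but -0.02 for the mean of the arrays. The gradient thus largely cancelled in that mean. Why print-tip loess moved the Gapdh mean was not tested. Other spots of the same brightness in those blocks had a median of 0.008764, which argues against brightness. A treatment effect on Gapdh, and a dye effect if the labels of 1 array are wrong, stay open, untested beyond this 1 pair of pools.

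The opposition between the arrays has several candidate explanations. Block medians ran from -0.18 in the first row of blocks to 0.17 in the last on array 1, and from 0.13 to -0.12 on array 2, but print-tip loess still left r = -0.299, which argues against this gradient as the whole cause. A dye effect of the single spot may contribute: the Gapdh spots, all of 1 gene, gave r = -0.3407 (95% interval -0.45 to -0.22) between the arrays after print-tip loess. Their r was -0.257 in the main setting and -0.568 with plain subtraction. The interval takes the spots as independent, though 226 of 227 lie in 4 blocks. Print-tip loess does not remove a gradient inside a block, so such a gradient is not excluded. The covariance of the Gapdh spots was 36.09% of that over the other spots (bootstrap interval 12.0% to 71.7%). The Gapdh and other spots were not matched on brightness or spread. In the main setting the SD on the arrays was 0.11 and 0.12 over Gapdh spots, against 0.20 and 0.25 over all features. The percent therefore does not divide the opposition among causes. A dye effect of the probe sequence and dyes exchanged in the labels of 1 array stay possible too, and cannot be told apart with 1 dye-exchanged pair. If the dyes of 1 array were exchanged, any treatment part would lie in the opposing component, which the 31 dye-following features head. That would not make each of these features a treatment effect, as their count ran from 15 with print-tip loess to 469 with median centring. No gene list of the 37 lay outside random lists (0) for that component.

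The probes that were not measured clustered by print position. Of the 1182 such probe spots, 990 (83.8%) lie at 31 of the 484 positions within a block, each dark in at least 10 of the 48 blocks, and 12 positions were dark in all 48. At the remaining positions 99.1% of the probe spots were measured. The dark positions hold the death receptor and BCL2-family genes Fas, Bax and Bcl2 and the cyclin genes Ccnd1 and Ccne1, chosen here after their values were seen.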
